A study of Arabidopsis thaliana with 18 samples.

How the data were processed

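RNA of Arabidopsis thaliana seedlings was measured on Affymetrix ATH1 arrays after biotin labelling of total RNA, per the labels' protocols. Seedlings grew on GM medium at 23 °C by day and 21 °C by night with 16 h of light and 8 h of dark, per the labels' protocols. The values used are log2 expression per probe set as deposited by the authors, made with RMA per the submitters' processing notes, with no version given. RMA corrects the background, applies quantile normalisation to the probes and summarises each probe set by median polish. Its settings, and whether the arrays of both genotypes were processed in a single run, are not given in the sources used here. The log2 scale was checked from the values, which ran from 2.63 to 14.6, with array medians of 6.48 to 6.55, lower quartiles of 4.26 to 4.39 and upper quartiles of 8.22 to 8.28. The largest gap of a sorted array to the mean sorted array was 0.189, and that between the mean sorted Col and bru1 arrays was 0.0938, below the largest gaps within Col (0.163) and within bru1 (0.165). No 2 arrays held identical columns. The deposited values were therefore used without further scaling. Such normalisation sets the arrays to nearly equal distributions, so a change of total RNA per seedling would not be seen.

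The 18 arrays fall into 6 groups of 3 by genotype (Col, bru1) and condition (untreated control, 4 h and 52 h after acclimation), as the labels give them, and the labels call the 3 biological replicates. Their number limits the precision, and exact permutation tests of 3 against 3 arrays cannot go below p = 0.1. All 18 arrays entered 1 model with a mean per group in limma 3.58.1 under R 4.3.3 (lmFit and eBayes), with 12 residual degrees of freedom. Comparisons were 4 h and 52 h against control in each genotype, bru1 against Col in each condition, and the interactions, which subtract the Col change from the bru1 change. P-values were adjusted by the Benjamini-Hochberg method over 22746 probe sets, after 64 AFFX control probe sets were left out, with a threshold of 0.05. A second count also required a change of at least 2-fold. The contrast of the change from 4 h to 52 h between genotypes was added after the data were seen.

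Genes were named from the probe table given with the data and from a RefSeq gene table on the assembly TAIR10.1, used for names only. Of the tested probe sets 13513 (59.4%) had 1 gene, 503 had several and 8730 are not listed there and stay unnamed here. Of the 1-gene probe sets 13436 matched a locus and 77 did not. They stand for 13355 genes, of which 147 had more than 1 probe set, and for these the probe set with the highest mean over all arrays was read. Probe sets with several genes were not named. Neither file names a build for the arrays, so no coordinates are given.

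The 9 comparisons, their tests, the alternatives listed below, 20 gene lists and the rule for named genes were set before the data were examined, and the text says what was added later. By this rule the text names up to 10 genes with the largest rise and up to 10 with the largest fall per comparison, among 1-gene probe sets past the threshold whose 3 arrays of one group all lie above or below those of the other, which chance alone gives to 10% of unchanged genes. For interactions it names up to 10 each way past the threshold. It also names every measured heat stress memory gene and up to 4 members of each other list with the largest changes. Members of lists named beyond these, such as a gene followed into a comparison where the rule does not select it, were chosen after their values were seen.

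Of 20 lists fixed before the data were examined, 6 had at least 3 members with a 1-gene probe set and were tested as sets. These were heat stress memory (4 of 11), small heat shock proteins (10 of 18), larger chaperones and co-chaperones (8 of 27), unfolded protein response (4 of 14), DNA damage (3 of 28) and photosynthesis (3 of 18). The lists for replication (2 of 23), mitosis (2 of 20), root hairs (2 of 8), dehydration and cold (2 of 13), silencing reporters (1 of 5), meristem (1 of 12), epidermis (1 of 8) and the circadian clock (1 of 15) are described by gene. Heat genes without memory, heat shock factors, memory regulators, seed maturation, vascular and salicylic acid lists had 0 members with a 1-gene probe set and are not analysed here. After the genes with the largest changes were seen, 6 lists were added, namely LEA (35 of 51), seed reserve (12 of 17), flavonoid (6 of 19), mitochondrial (16) and plastid (69) genome genes and pseudogenes (989). The lists were tested with camera of limma at a preset correlation between genes of 0.01, with the correlation estimated from the data beside it and with fry, and adjusted over the lists of each kind within a comparison. Of the fixed lists, 16 calls over 9 comparisons passed with the preset and 8 with the estimated correlation, and of the added lists 26 and 4.

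The linear model steps were tested on simulated data with known changes in 200 of 22746 probe sets per comparison. For changes of 1 on the log2 scale, 92.5% (Col at 4 h and at 52 h) to 97.0% (bru1 at 52 h) were recovered in comparisons of 2 groups, and 70.1% and 71.6% in the interactions at 4 h and 52 h. For changes of 0.5, 23.9% (Col at 52 h) to 41.8% (bru1 against Col, control) were recovered, and 4.48% and 7.46% in the interactions. For changes of 2 all were recovered. False calls numbered 4 (interaction at 4 h) to 11 (bru1 against Col at 52 h).

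Alternatives were quantile normalisation of all arrays, median centring of each array, removal of the dimmest 25% of probe sets, array weights, trend and robust eBayes, fits on only the groups compared, the replicate number as a block, a minimum change, and leaving out each array in turn. Shared-control overlaps were compared with the overlap of independent lists and with 20 simulations without effect, in which lists of the observed sizes were taken by the largest changes, a choice made after the data were seen. Signs of RNA quality were read from AFFX control probe sets. The BRU1 transcript, transposable element and ribosomal protein lists were not analysed here. No further columns of values per sample were left unused.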

Results

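Transcript levels were measured on Affymetrix ATH1 arrays in Arabidopsis thaliana seedlings of the Columbia wild type (Col) and of the bru1 mutant. BRU1, also known as TONSOKU, is a nuclear protein needed for genome maintenance during replication. The series title ties it to heat stress memory, the lasting state that follows a first, survivable heat treatment. Seedlings aged 4 d were acclimated at 37 °C for 1 h, 23 °C for 1.5 h and 44 °C for 45 min, starting 6 h after dawn. RNA came from untreated seedlings at the 4 h time point (control) and from seedlings 4 h or 52 h after acclimation, all harvested at a matching time of day. Each of the 6 groups held 3 biological replicates, which gave 18 arrays, and the number of arrays limits the precision. Array medians lay between 6.48 and 6.55 on the log2 scale, and the mean correlation of an array with the others of its group lay between 0.986 and 0.996. Of the 22746 probe sets tested, 13513 had 1 gene in the table used here. The labels give no hybridisation run, so any run that differed between genotypes cannot be told apart from the genotype in direct comparisons of bru1 with Col. A shift common to all arrays of a genotype drops out of the interactions. The BRU1 transcript was not analysed here, so the genotype labels have no check from the mutated gene. Group values below are log2 expression as mean ± SD over 3 arrays, changes are log2 fold changes ± SE from limma, and p-values are adjusted by the Benjamini-Hochberg method unless stated otherwise. Detection calls were not used here. A group mean no higher than the highest lower quartile of the arrays, 4.39, is not shown to be above background, and the change of such a gene is called a lower bound. A list past the threshold that is given with a single p also passed with an estimated correlation between its genes.

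The response of wild-type seedlings 4 h after acclimation was led by transcripts of small heat shock proteins, chaperones that hold unfolding proteins. HSP17.6C (AT1G53540) rose from 4.34 ± 0.20 to 13.54 ± 0.20, a change of at least 9.20 ± 0.42 (adjusted p = 2.7e-11, n = 3 a group), and the endoplasmic reticulum chaperone HSP22 (AT4G10250) rose by 8.08 ± 0.28 (adjusted p = 1.1e-12). Among the 10 small heat shock protein genes measured, 8 rose and 0 fell, with a median change of 5.12 (camera adjusted p = 3.5e-10). Adjusted over the list alone, 8 rose and 1 fell. HSP17.6B-CI (6.80), HSP26.5 (6.76) and HSP17.4-CIII (5.71) were among those that rose, while HSP15.4 (0.42) and HSP14.2 (-0.47) did not pass the test. The value of HSP26.5 is a lower bound. Of the 8 measured genes for larger chaperones and co-chaperones 4 rose, the immunophilin gene ROF2 by 6.34 ± 0.16 (adjusted p = 2.6e-14), and HOP3 (5.53), FES1A (2.49) and HOP2 (0.90), which assist the HSP70 and HSP90 systems. That list had a median change of 0.79 (camera adjusted p = 0.0017, adjusted p = 0.25 with an estimated correlation), or 0.48 without Col 4 h replicate 2, and adjusted over the list alone 4 rose and 1 fell. Transcripts of the mitochondrial genome, which encodes subunits of the respiratory complexes, were also higher in Col at 4 h. nad6 rose by at least 8.15 ± 0.31, nad5 by at least 7.53 ± 0.29 and cox1 by 6.07 ± 0.20. Of 16 mitochondrial genes, a list added after the data were seen, 14 rose with a median of 3.33 (camera adjusted p = 1.8e-17). Of 69 plastid genes, also a list added after the data were seen, 10 rose and 29 fell. The photosystem genes psaA (2.40) and psbB (1.83) were among the first, and the polymerase gene rpoC1 (-2.67) and the ribosomal protein gene rps18 (-2.78) were among the second. The plastid median was -0.37 (camera adjusted p = 0.0015, adjusted p = 0.50 with an estimated correlation), or -0.16 without Col 4 h replicate 2. The control probe set for 25S ribosomal RNA, a sign of how much non-polyadenylated RNA was labelled, was likewise higher, at 12.82 ± 0.40 against 11.50 ± 0.20 in the controls (difference 1.32, exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). The 3' minus 5' differences of the GAPDH and actin control probe sets, signs of RNA degradation, were higher as well, by 0.21 and 0.55 (exact permutation p = 0.1 for each). Whether more labelling of non-polyadenylated RNA, rather than higher transcript levels, lies behind the mitochondrial rises here and below was not tested.

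The transcripts that fell most in Col at 4 h included those of enzymes of flavonoid and anthocyanin synthesis. DFR fell by 6.34 (SE 0.48, adjusted p = 1.8e-08), UF3GT by 4.40 and AT4G14090, an anthocyanin glucosyltransferase gene, by 4.70. All 6 measured genes of the flavonoid list, added after the data were seen, fell, with a median of -3.86 (camera adjusted p = 1.7e-08, adjusted p = 0.056 with an estimated correlation). AT1G65490 (-6.21), AT1G60590 (-5.07), AT1G23205 (-5.06) and AT2G25510 (-4.56) also fell. The falls of DFR and AT1G23205 are lower bounds in size. None of the 4 measured genes of the unfolded protein response of the endoplasmic reticulum passed the test in limma, adjusted over all probe sets, adjusted over the list alone or unadjusted (median 0.10, camera adjusted p = 0.92). In all, limma called 4144 probe sets higher and 4130 lower than in the controls at an adjusted p under 0.05, and 9972 lay under an unadjusted p of 0.05. Of the called ones, 649 were at least 2-fold higher and 1160 at least 2-fold lower. All 22 genes named by rule for this comparison and past the threshold stayed so when any single array was left out.

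**Figure D1:**
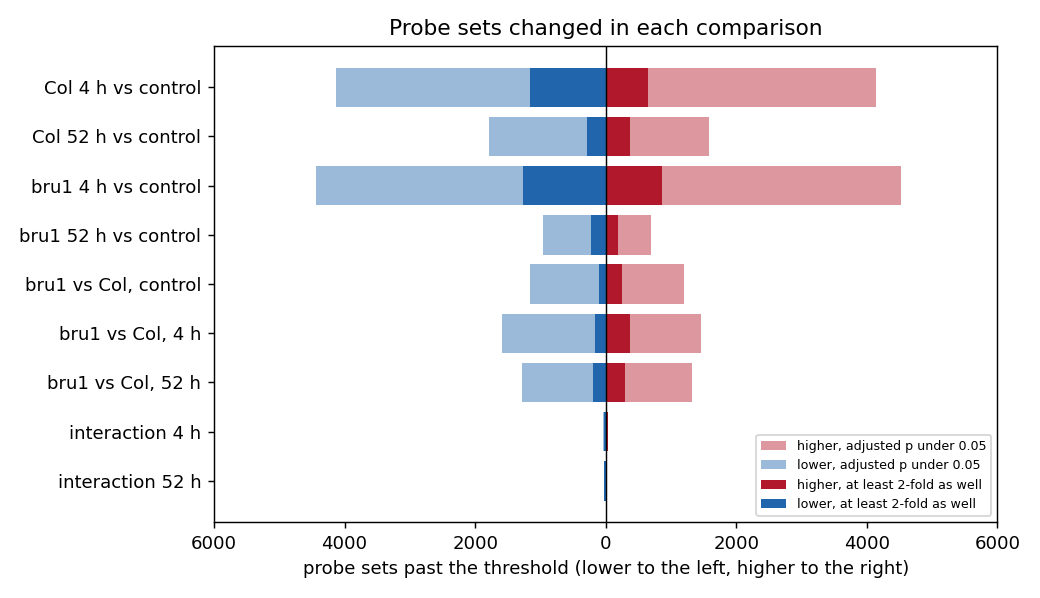
Numbers of probe sets lower (left) and higher (right) at an adjusted p under 0.05 in limma for the 9 comparisons, with those that also changed at least 2-fold as the darker bars. The 4 h responses called 8274 (Col) and 8957 (bru1) probe sets, the 52 h responses 3360 and 1647, and the tests of a different response in bru1 78 at 4 h and 27 at 52 h.

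At 52 h after acclimation, small heat shock protein transcripts were still high in wild-type seedlings. HSP17.6C stood at 10.17 ± 1.03, which is at least 5.83 ± 0.42 above the controls (adjusted p = 1.6e-07), HSP22 at 10.04 ± 0.71 (5.25 ± 0.28 above) and HSP15.7 (AT5G37670) at 10.20 ± 0.46 (4.09 ± 0.37 above, after 4.28 at 4 h). HSA32 (AT4G21320), which encodes a heat-induced protein needed for acquired thermotolerance to last, was 2.35 ± 0.23 above the controls. These are the 4 measured genes of the heat stress memory list, 3 of which are also on the small heat shock protein list, and all 4 rose at 52 h (median 4.67, camera adjusted p = 1.1e-11). They had also risen at 4 h (camera adjusted p = 4.9e-08). Adjusted over the list alone, 4 rose at each time. Of the 10 small heat shock protein genes 7 rose, or 9 adjusted over the list alone (median 2.62, camera adjusted p = 7.8e-14). Of the 8 larger chaperone genes 2 were above the control level at 52 h, HOP3 (1.91) and ROF2 (2.46), and the list had a median of 0.02 and a mean of 0.45 (camera adjusted p = 0.25).

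Outside the chaperones, the defensin gene PDF1.4 rose by 4.61 ± 0.42 and AT2G04050, which encodes a MATE family transporter, by 4.30 ± 0.51 in Col at 52 h. Mitochondrial transcripts were above the controls in 9 of 16 genes, all 9 of which had also risen at 4 h, or in 11 adjusted over the list alone, with nad6 at no less than 3.60 and nad5 at no less than 3.48 (median 0.91, camera adjusted p = 6.3e-12, adjusted p = 0.11 with an estimated correlation). The 25S ribosomal RNA control was 0.77 higher, and the 3' minus 5' differences 0.071 (GAPDH) and 0.44 (actin) higher (exact permutation p = 0.1 for each). Flavonoid genes remained lower, with 4 of 6 past the threshold and 6 adjusted over the list alone, for example UF3GT (-1.45) and AT5MAT (-1.43), and a median of -1.20 (camera adjusted p = 4.9e-04, adjusted p = 0.31 with an estimated correlation). That median was -0.51 without Col 52 h replicate 3, on which DFR stood at 7.80 against 9.91 and 10.85 on the other Col 52 h arrays. Among the transcripts that fell were those of the chitinase family members AT2G43590 (-2.22) and AT1G02360 (-1.86) and of AT3G13610 (-1.77), a dioxygenase of scopoletin synthesis. In all, 1577 probe sets were higher and 1783 lower, 366 and 283 of them by at least 2-fold, and 6260 lay under an unadjusted p of 0.05. The seedlings sampled at 52 h were about 2 days older than the controls, so age and treatment go together within a genotype.

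**Figure D2:**
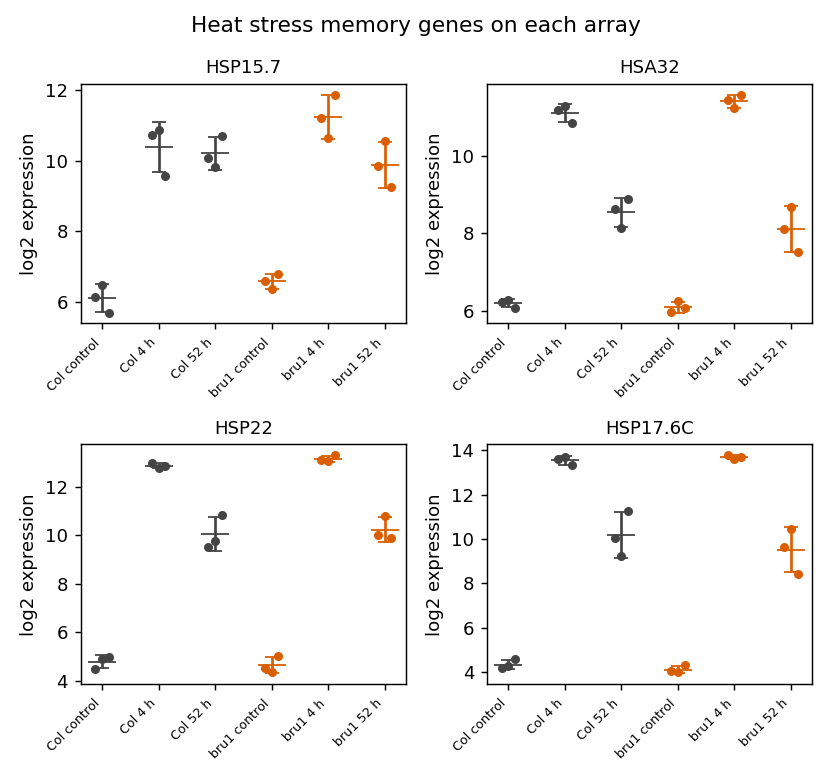
Log2 expression of the heat stress memory genes HSP15.7, HSA32, HSP22 and HSP17.6C on each array of the 6 groups, with the group mean as a horizontal line and bars of 1 SD (n = 3). In both genotypes each gene lies above its controls at 4 h and at 52 h, and the bru1 means at 52 h lie within 0.67 log2 units of the Col means.

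The heat response of bru1 seedlings 4 h after acclimation was led by small heat shock protein transcripts as well. HSP17.6C rose by at least 9.58 ± 0.42, HSP22 by 8.51 ± 0.28, HSP26.5 by at least 8.01 ± 0.49 and the mitochondrial small heat shock protein gene HSP23.5 by 5.80 ± 0.39 (adjusted p = 4.1e-09). Of the 10 small heat shock protein genes 8 rose, or 9 adjusted over the list alone (median 5.51, camera adjusted p = 2.7e-10). All 4 memory genes rose, adjusted over the list alone as well (median 6.92, camera adjusted p = 8.2e-08). Of the 8 larger chaperone genes, 6 rose, or 7 adjusted over the list alone, among them HOP3 (5.71), FES1A (4.37) and the HSP70 gene HSC70-3 (2.10), with a median of 1.80 (camera adjusted p = 7.1e-06, adjusted p = 0.082 with an estimated correlation). All 4 measured genes of the unfolded protein response rose in bru1, adjusted over all probe sets and over the list alone. They were the transcription factor genes BZIP28 (1.48 ± 0.29, adjusted p = 4.6e-04) and BZIP60 (0.89 ± 0.22), and the chaperone genes ERDJ3B (0.66 ± 0.16) and CRT2 (0.37 ± 0.12), with a median of 0.78 (camera adjusted p = 0.019, adjusted p = 0.29 with an estimated correlation). Whether these responses differ from those of Col is tested below by the interaction.

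Mitochondrial transcripts rose in 15 of 16 genes in bru1 at 4 h, with nad6 at no less than 7.61 and nad5 at no less than 7.47 (median 3.11, camera adjusted p = 2.1e-17). The 25S ribosomal RNA control was 2.12 higher and the actin 3' minus 5' difference 0.48 higher (exact permutation p = 0.1 for each), while that of GAPDH changed by -0.075 (exact permutation p = 0.3). Plastid transcripts fell in 39 of 69 genes and rose in 0, for example rps18 (-3.37) and rpl33 (-2.90), with a median of -0.69 (camera adjusted p = 1.6e-11, adjusted p = 0.12 with an estimated correlation). All 6 flavonoid genes fell, among them DFR (-6.41), UF3GT (-4.86) and CHIL (-4.02), with a median of -4.44 (camera adjusted p = 6.8e-09, adjusted p = 0.052 with an estimated correlation). BCAT4, an enzyme gene of glucosinolate chain elongation, fell by 3.96. Genes for late embryogenesis abundant (LEA) proteins, which protect cells in drying seeds, rose in 14 of 35 cases and fell in 0 (median 0.26, camera adjusted p = 0.0018, adjusted p = 0.16 with an estimated correlation), on a list added after the data were seen. In Col at 4 h, 5 of the 35 had risen and 5 had fallen. In all, 4522 probe sets were higher and 4435 lower, 862 and 1272 of them by at least 2-fold, and 10482 lay under an unadjusted p of 0.05. Across all 22746 probe sets the 4 h changes of both genotypes correlated with r = 0.887 (jackknife SE 0.0368) and a slope of bru1 on Col of 0.96, a description across genes, which are not independent replicates. Of the probe sets at least 2-fold higher at 4 h, 467 were so in both genotypes (24.6 for independent lists), and of those at least 2-fold lower 877 were (64.9 for independent lists).

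**Figure D3:**
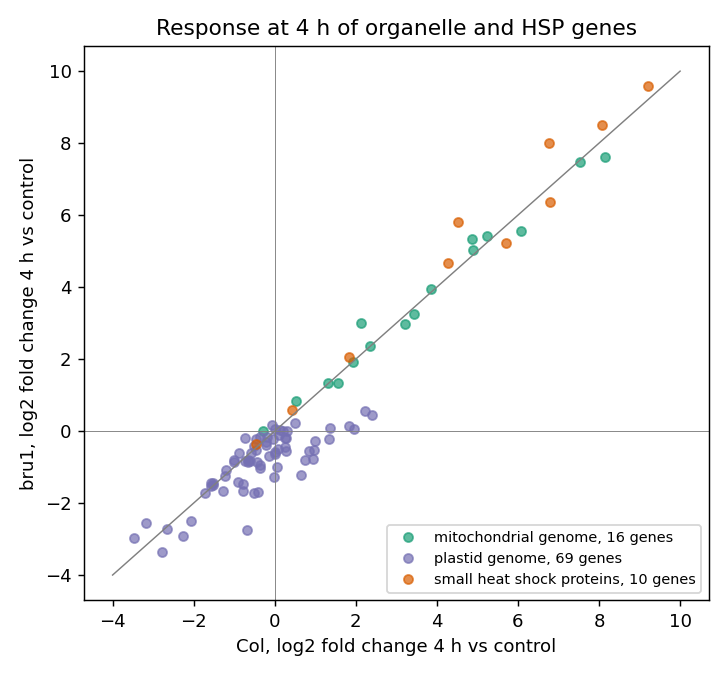
Log2 fold changes at 4 h against control in Col (x axis) and bru1 (y axis), with the line of equality. Points are 16 mitochondrial genes (green), 69 plastid genes (purple) and 10 small heat shock protein genes (orange). Of the mitochondrial genes 14 rose in Col and 15 in bru1, of the small heat shock protein genes 8 rose in each, and the plastid genes had a median of -0.37 in Col and -0.69 in bru1.

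At 52 h in bru1 small heat shock protein transcripts were still above their controls. HSP22 was 5.58 ± 0.28 (adjusted p = 2.1e-09), HSP17.6C at least 5.39 ± 0.42 (adjusted p = 6.0e-07), HSP15.7 3.31 ± 0.37 and HSA32 2.02 ± 0.23 above the bru1 controls. All 4 memory genes rose, adjusted over the list alone too (median 4.35, camera adjusted p = 4.9e-14). Of the 10 small heat shock protein genes 6 rose, or 9 adjusted over the list alone (median 1.83, camera adjusted p = 4.9e-14). Of the 8 larger chaperone genes 2 rose, HOP3 (1.27) and ROF2 (1.89). That list had a median of -0.04, a mean of 0.28 and a camera test in the direction of the mean (camera adjusted p = 0.43). PDF1.4 rose by 2.99 ± 0.42. Mitochondrial genes rose in 8 of 16 cases, or 9 adjusted over the list alone (median 0.61, camera adjusted p = 1.7e-11, adjusted p = 0.12 with an estimated correlation). The 25S ribosomal RNA control was 1.05 higher (exact permutation p = 0.1), and the 3' minus 5' differences changed by 0.031 (GAPDH, exact permutation p = 0.7) and -0.019 (actin, exact permutation p = 0.6). None of the 6 flavonoid genes passed the test in limma, adjusted over all probe sets, adjusted over the list alone or unadjusted (median 0.01, camera adjusted p = 0.90). Transcripts that fell included the thionin gene AT1G66100 (-2.70), AT2G47200 (-2.15) and AT1G74460 (-2.07). In all, 693 probe sets were higher and 954 lower, 193 and 219 of them by at least 2-fold, and 4396 lay under an unadjusted p of 0.05. The total of 1647 fell to 843 without bru1 52 h replicate 1 and to 960 without bru1 control replicate 2. The 52 h changes of both genotypes correlated across probe sets with r = 0.733 (jackknife SE 0.0342), or 0.687 without bru1 52 h replicate 2, and the slope of bru1 on Col was 0.60.

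Before any heat treatment, bru1 seedlings differed from Col, with genes for LEA proteins among those higher in bru1. M17, a LEA gene, was at least 2.84 ± 0.66 higher in bru1 (adjusted p = 0.010), LEA18 2.23 ± 0.31 higher (adjusted p = 1.2e-04) and AT3G54940, a cysteine protease family gene, 2.70 ± 0.18 higher (adjusted p = 1.2e-07). Of 35 LEA genes 10 were higher and 0 lower, or 13 higher adjusted over the list alone (median 0.27, camera adjusted p = 2.8e-06, adjusted p = 0.11 with an estimated correlation). The LEA median was 0.17 without Col control replicate 2. Of 12 seed reserve genes, also a list added after the data were seen, 3 were higher, among them the oleosin gene AT2G25890 (1.80) and the seed storage protein family gene AT2G28490 (1.79), with a median of 0.27 (camera adjusted p = 0.0057, adjusted p = 0.24 with an estimated correlation), which was 0.091 without bru1 control replicate 2 and 0.41 without bru1 control replicate 3. Adjusted over the list alone, 4 were higher. The peroxidase gene AT5G64120 was lower in bru1 (-2.62 ± 0.37), as were AT1G13650 (-2.75), AT2G33850 (-2.39) and AT4G22490 (-2.11), the last 2 as lower bounds in size. LIG4, the ligase of DNA end joining, was 0.76 ± 0.11 higher (adjusted p = 1.4e-04) and the meiotic recombination gene MND1 0.49 ± 0.13 higher (adjusted p = 0.022). They are 2 of the 3 measured genes of the DNA damage list, and the count adjusted over the list alone was also 2 (median 0.49, camera adjusted p = 0.10). None of the 4 memory genes or 10 small heat shock protein genes passed the test in limma between the untreated genotypes, and 0 and 4 of them lay under an unadjusted p of 0.05. Plastid genes were higher in 7 of 69 cases and lower in 0 (median 0.14, camera adjusted p = 9.4e-05, adjusted p = 0.47 with an estimated correlation), with a median of 0.083 without Col control replicate 3. In all, 1192 probe sets were higher and 1160 lower in bru1, 255 and 102 of them by at least 2-fold, and 5491 lay under an unadjusted p of 0.05. The 3' minus 5' difference was 0.67 ± 0.10 in bru1 and 0.41 ± 0.05 in Col controls for GAPDH, and 3.03 ± 0.06 and 2.73 ± 0.06 for actin (exact permutation p = 0.1 for each). The total of 2352 was 1505 without Col control replicate 1, 1495 without Col control replicate 2, 1486 without bru1 control replicate 1 and 1564 without bru1 control replicate 3. The call of the iron-deficiency peptide gene AT1G47400 (2.00 ± 0.51) was lost in 3 of 6 such refits, with a change of 1.44 without bru1 control replicate 1.

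The same comparison of genotypes 4 h after acclimation again showed LEA genes higher in bru1. AT3G54940 was at least 4.16 ± 0.18 higher (adjusted p = 2.9e-10), the LEA genes AT4G21020 at least 3.34 ± 0.22, AT3G15670 3.23 ± 0.31 and LEA18 3.14 ± 0.31 higher, and ICL, the isocitrate lyase of the glyoxylate cycle, 2.92 ± 0.39 higher. Of 35 LEA genes 17 were higher and 0 lower, or 18 higher adjusted over the list alone (median 0.47, camera adjusted p = 1.0e-12). Of 12 seed reserve genes 4 were higher (median 0.69, camera adjusted p = 8.4e-05, adjusted p = 0.061 with an estimated correlation). In Col 3 of the 12 had fallen from control to 4 h and 0 had risen, or 2 and 0 adjusted over the list alone (median -0.36, camera adjusted p = 0.049, adjusted p = 0.40 with an estimated correlation). Adjusted over the list alone, 5 seed reserve genes were higher and 1 lower. FES1A (1.29 ± 0.39), HSC70-3 (1.09 ± 0.30) and HOP2 (0.55 ± 0.18) were higher in bru1 among the 8 larger chaperone genes, which gave 5 higher adjusted over the list alone (median 0.44, camera adjusted p = 0.026, adjusted p = 0.36 with an estimated correlation). Of the 4 unfolded protein response genes BZIP28 (1.25 ± 0.29) and BZIP60 (0.91 ± 0.22) were higher, over all probe sets and over the list alone (median 0.61, camera adjusted p = 0.020, adjusted p = 0.36 with an estimated correlation). The plastid photosystem genes psaA (-2.12 ± 0.42) and psbD (-2.03 ± 0.31) were lower in bru1. Of 69 plastid genes 13 were lower and 2 higher, or 17 and 3 adjusted over the list alone (median -0.05, camera adjusted p = 0.071). Of 16 mitochondrial genes 1 was higher in bru1, matR at 0.66, with a median of 0.16 (camera adjusted p = 0.044, adjusted p = 0.79 with an estimated correlation), or 0.26 without Col 4 h replicate 1 and 0.24 without bru1 4 h replicate 1. The Col 4 h arrays held psbD at 10.8, 9.23 and 10.9 for replicates 1 to 3. LIG4 was 0.87 ± 0.11 higher, the 1 DNA damage gene of 3 past the threshold (median 0.20, camera adjusted p = 0.034, adjusted p = 0.27 with an estimated correlation). The 25S ribosomal RNA control was 13.25 ± 0.01 in bru1 and 12.82 ± 0.40 in Col, and the actin 3' minus 5' difference 3.51 ± 0.07 and 3.27 ± 0.15 (exact permutation p = 0.1 for each). That of GAPDH was 0.60 ± 0.03 and 0.62 ± 0.09 (exact permutation p = 0.8). None of the 4 memory genes passed the test in limma, and 1 lay under an unadjusted p of 0.05 (median 0.30, camera adjusted p = 0.15). In all, 1466 probe sets were higher and 1582 lower, 376 and 163 of them by at least 2-fold, and 5986 lay under an unadjusted p of 0.05. The total of 3048 was 1715 without Col 4 h replicate 1, 1826 without Col 4 h replicate 3, 1964 without bru1 4 h replicate 1 and 1764 without bru1 4 h replicate 3.

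At 52 h LEA genes were higher in bru1 once more, and flavonoid genes were higher too. AT3G02480, a LEA family gene, was 3.39 ± 0.24 higher (adjusted p = 8.2e-08), AT3G15670 at least 3.18 ± 0.31 and LEA18 2.99 ± 0.31 higher. Of 35 LEA genes 13 were higher and 1, DI21 (-0.62), was lower, with 14 higher and 1 lower adjusted over the list alone (median 0.20, camera adjusted p = 9.9e-09). The LEA median was 0.31 without Col 52 h replicate 3. Of 12 seed reserve genes 5 were higher, or 6 adjusted over the list alone (median 0.52, camera adjusted p = 5.6e-05, adjusted p = 0.066 with an estimated correlation). All 6 flavonoid genes were higher in bru1, with DFR at 2.02 ± 0.48 and UF3GT at 1.91 ± 0.33 (median 1.66, camera adjusted p = 1.1e-06, adjusted p = 0.071 with an estimated correlation). Col 52 h replicate 3 stood apart in these genes, with a list median of 7.53 against 9.37 and 9.81 on the other Col 52 h arrays, and without it the median difference was 1.11. AT4G22490, which encodes a lipid transfer protein family member, was lower in bru1 (-4.36 ± 0.17, adjusted p = 9.1e-11), as were AT2G33850 (-4.15 ± 0.23), the MATE transporter gene AT2G04050 (-3.22 ± 0.51), AT2G18190 (-2.59 ± 0.32) and PDF1.4 (-2.28 ± 0.42). The value of AT4G22490 is a lower bound in size. Plastid genes were higher in 8 of 69 cases and lower in 0, with 9 higher adjusted over the list alone (median 0.20, camera adjusted p = 4.5e-06, adjusted p = 0.27 with an estimated correlation). The plastid median was 0.13 without bru1 52 h replicate 2 and 0.31 without bru1 52 h replicate 3. LIG4 was 0.77 ± 0.11 higher. Among chaperones ROF2 was lower (-0.61 ± 0.16, adjusted p = 0.022), and none of the 4 memory genes passed the test in limma, adjusted over all probe sets, adjusted over the list alone or unadjusted (median -0.38). The GAPDH 3' minus 5' difference was 0.70 ± 0.05 in bru1 and 0.48 ± 0.06 in Col (exact permutation p = 0.1), whereas that of actin went the other way, at 3.01 ± 0.08 and 3.17 ± 0.28 (exact permutation p = 0.5). In all, 1328 probe sets were higher and 1287 lower, 291 and 187 of them by at least 2-fold, and 5690 lay under an unadjusted p of 0.05. The total of 2615 was 1549 without bru1 52 h replicate 1 and 1684 without bru1 52 h replicate 3. The call of AT4G36700 (2.85 ± 0.76) was lost in 3 of 6 such refits, with a change of 2.37 without bru1 52 h replicate 1. Over control, 4 h and 52 h, 470 probe sets were higher in bru1 each time (4.49 for independent lists) and 274 lower each time (4.56 for independent lists), 101 and 33 of them by at least 2-fold each time.

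**Figure D4:**
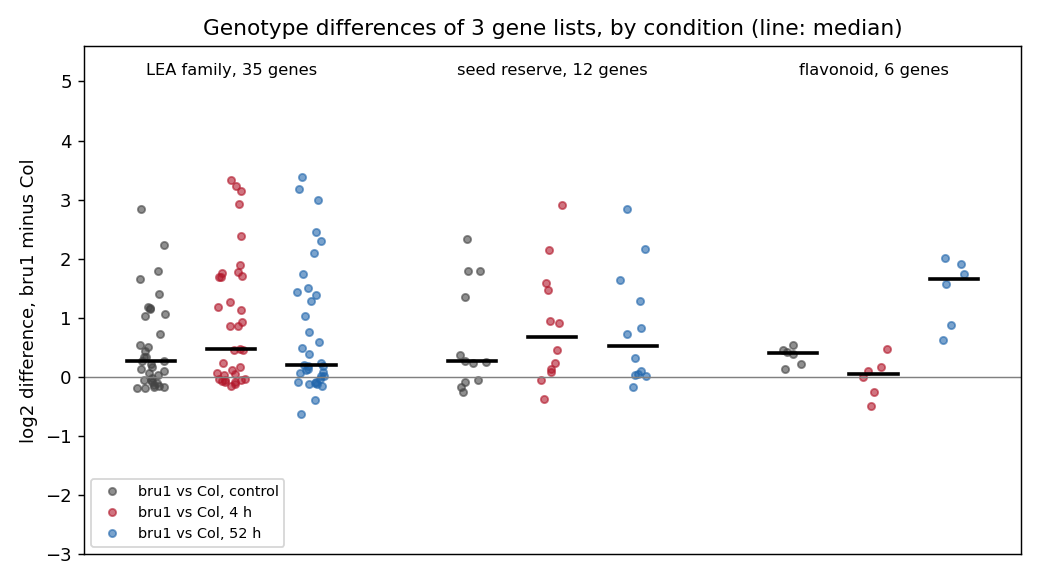
Difference between bru1 and Col in log2 expression (y axis) for each of 35 LEA, 12 seed reserve and 6 flavonoid genes (points) in untreated controls, at 4 h and at 52 h, with the list median as a line. The LEA medians are 0.27, 0.47 and 0.20, and the flavonoid median is 1.66 at 52 h.

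Whether the 4 h response itself differed between the genotypes was tested as an interaction, the change in bru1 minus the change in Col. The zinc finger gene STZ (ZAT10) had the largest positive difference among named genes, 2.86 ± 0.56 (adjusted p = 0.041), with 2.16 in bru1 and -0.70 in Col, the latter not past the test. AT2G21640, a marker of oxidative stress, differed by 2.24 ± 0.47, and LEA family members AT3G15670 by 2.08 ± 0.43, AT3G53040 by 1.66 ± 0.31 and the gene named LEA (AT2G21490) by 1.43 ± 0.27, with a Col 4 h mean of LEA not shown to be above background. In the other direction AT2G32150 differed by -2.13 ± 0.26 (adjusted p = 0.0046), a change of 0.53 in Col and -1.60 in bru1, and GAT1_2.1 by -1.71 ± 0.23, 0.82 in Col and -0.90 in bru1. Of 35 LEA genes 5 had a positive difference past the test, or 6 adjusted over the list alone (median 0.20, camera adjusted p = 8.8e-05, adjusted p = 0.25 with an estimated correlation). No gene of the unfolded protein response passed over all probe sets in limma, while all 4 did adjusted over the list alone and unadjusted, led by BZIP28 (1.43 ± 0.40), with a list median of 0.58 (camera adjusted p = 0.0018, adjusted p = 0.33 with an estimated correlation). The 8 larger chaperone genes gave a median of 0.42 (camera adjusted p = 0.0070, adjusted p = 0.33 with an estimated correlation) with FES1A at 1.88 ± 0.55 and HSC70-3 at 1.42 ± 0.42. Of these 8 genes 2 passed adjusted over the list alone and 0 over all probe sets in limma, with 4 under an unadjusted p of 0.05. Plastid genes had a median of -0.39 (camera adjusted p = 8.7e-09, adjusted p = 0.28 with an estimated correlation), with 0 of 69 past the test over all probe sets in limma, 27 under an unadjusted p of 0.05, and 18 lower adjusted over the list alone, for example psbD (-1.89 ± 0.44). The 4 memory genes had a median of 0.39 (camera adjusted p = 0.26), and none passed in limma over all probe sets, over the list alone or unadjusted.

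Over all probe sets the 4 h interaction called 40 with a positive and 38 with a negative difference, 29 and 21 of them by at least 2-fold, and 2966 lay under an unadjusted p of 0.05. Of the 20 genes named by rule, AT2G32150, GAT1_2.1, AT5G43520 and AT2G44380 stayed past the threshold in all 12 refits without 1 array, and 16 did not. The total of 78 moved by more than 1.5 times in every such refit, as follows. It was 11, 36 and 22 without Col control replicates 1, 2 and 3, and 7, 301 and 20 without Col 4 h replicates 1, 2 and 3. It was 35, 29 and 9 without bru1 control replicates 1, 2 and 3, and 12, 405 and 10 without bru1 4 h replicates 1, 2 and 3.

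The interaction at 52 h asked whether the lasting response differed in bru1, and at this time the heat stress memory genes did not pass the test of a difference in limma. The differences were -0.79 ± 0.52 for HSP15.7 (adjusted p = 0.72), -0.33 ± 0.32 for HSA32 (adjusted p = 0.83), 0.33 ± 0.40 for HSP22 (adjusted p = 0.87) and -0.44 ± 0.59 for HSP17.6C (adjusted p = 0.89). Their 95% intervals were -1.89 to 0.31, -1.01 to 0.34, -0.51 to 1.16 and -1.68 to 0.79, in this order. Over the 12 refits without 1 array the differences ran from -1.12 to -0.48 for HSP15.7, from -0.62 to -0.038 for HSA32, from 0.044 to 0.73 for HSP22 and from -0.92 to 0.10 for HSP17.6C. The value nearest to 0 came without bru1 52 h replicate 3 for HSP15.7 and HSA32 and without bru1 52 h replicate 2 for HSP22, and HSP17.6C turned positive without Col 52 h replicate 3 (0.10) or bru1 52 h replicate 3 (0.097). The list gave a median of -0.39 (camera adjusted p = 0.31), and 0 of 4 passed in limma adjusted over the list alone or unadjusted. That median was -0.77 without bru1 52 h replicate 2, where the unadjusted camera p was 0.011 at the preset correlation (0.26 with all arrays) but 0.15 with an estimated correlation (0.53 with all arrays). It was 0.029 without bru1 52 h replicate 3, and it was -0.03 without Col 52 h replicate 3. The 10 small heat shock protein genes had a median of -0.37 (camera adjusted p = 0.12). Of these 1, HSP17.4-CIII (-1.12 ± 0.33), passed adjusted over the list alone but none over all probe sets in limma, with 2 under an unadjusted p of 0.05.

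Genes that did pass the 52 h interaction mostly had a negative difference. AT3G05600 rose by 1.03 in Col and fell by 1.69 in bru1, a difference of -2.72 ± 0.29 (adjusted p = 2.8e-04). AT4G22490 rose by 2.14 in Col and had -0.11 in bru1, a difference of -2.25 ± 0.25 (adjusted p = 2.8e-04). AT2G18190 (-2.72 ± 0.45), the thionin genes THI2.2 (-2.03 ± 0.34) and AT1G66100 (-1.76 ± 0.29) and AT5G33370 (-1.45 ± 0.26), of a lipase family that holds a cutin synthase, also had negative differences. The LEA gene AT3G02480 (2.21 ± 0.34) and AT4G36600 (1.18 ± 0.15) had positive ones. AT4G22490, AT5G33370 and AT4G36600 each had a group mean not shown to be above background. Of 35 LEA genes 2 passed with a positive difference (median 0.12, camera adjusted p = 0.017, adjusted p = 0.46 with an estimated correlation), while 4 higher and 2 lower passed adjusted over the list alone. The LEA median was 0.024 without bru1 52 h replicate 2 and 0.18 without bru1 control replicate 1. Flavonoid genes had a median of 1.25 (camera adjusted p = 3.2e-05, adjusted p = 0.33 with an estimated correlation), with 0 of 6 past the test in limma over all probe sets, 4 under an unadjusted p of 0.05 and 3 adjusted over the list alone. The flavonoid median was 0.64 without Col 52 h replicate 3. Mitochondrial genes had a median of -0.34 (camera adjusted p = 0.016, adjusted p = 0.46 with an estimated correlation), with 0 of 16 past the test in limma over all probe sets or over the list alone and 2 under an unadjusted p of 0.05. Their median was -0.088 without Col 52 h replicate 3 and -0.10 without bru1 52 h replicate 3. In all, limma called 4 probe sets with a positive and 23 with a negative difference, 3 and 22 of them by at least 2-fold, and 2079 lay under an unadjusted p of 0.05. Of the 12 genes named by rule, AT4G36600, AT3G05600 and AT4G22490 stayed past the threshold in all 12 refits without 1 array. The total of 27 was 10 and 13 without Col control replicates 1 and 2, 12, 13 and 12 without bru1 control replicates 1, 2 and 3, 8 without Col 52 h replicate 1 and 142 without Col 52 h replicate 2.

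**Figure D5:**
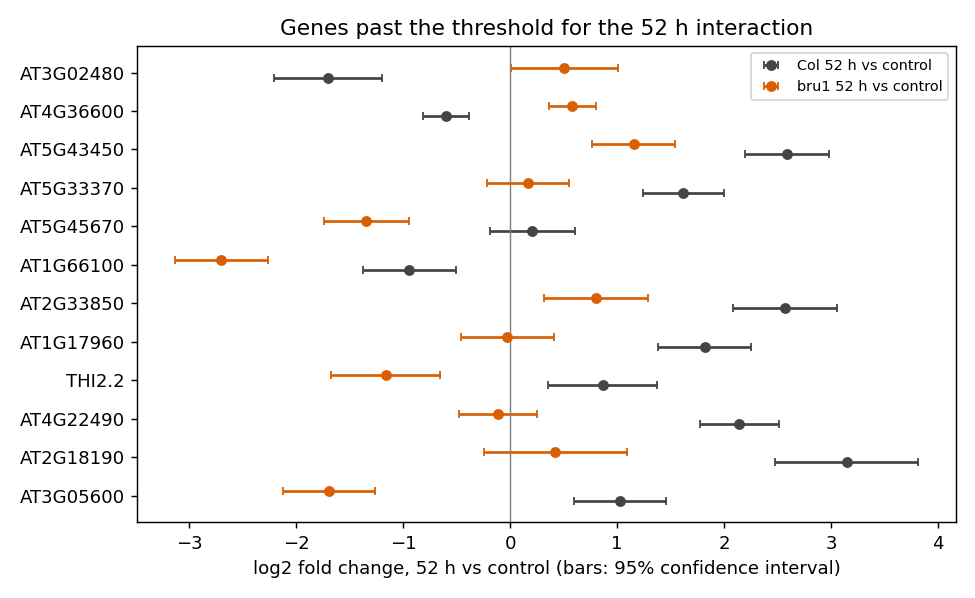
Log2 fold change at 52 h against control (x axis) in Col and in bru1, with 95% confidence intervals, for the 12 named genes past the threshold of the 52 h interaction. AT3G02480 and AT4G36600 lie higher in bru1 and the other 10 lie lower.

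Genes that stayed at least 2-fold above the control at both 4 h and 52 h numbered 145 probe sets in Col (10.4 for independent lists) and 87 in bru1 (7.31 for independent lists), with 71 in both. The comparisons at 4 h and 52 h share control arrays, which are too few to split. In 20 simulations without effect, lists of the same sizes were taken by the largest rises alone, without a test. They shared a mean of 134 probe sets in Col (highest 147) and 92.9 in bru1 (highest 107). The observed lists also had to pass an adjusted p under 0.05. With these thresholds the highest simulated overlap was 0, as almost nothing passes without effect. Neither way of choosing lists matches the observed ones, so the share of the 145 and of the 87 that comes from the shared controls is not decided. The Col and bru1 lists share no array, and the 71 in both compare with 0.555 for independent lists. For these 71, that argues against the shared controls as the whole cause. For the 145 chosen in Col, the median change at 52 h was 1.67 in Col and 1.11 in bru1, and 136 had a negative interaction, 2 of them past the test, with a median of -0.59. Choosing genes by their Col values favours higher Col values, and for the 87 chosen in bru1 the median interaction was -0.33, with 66 negative. For genes chosen on 2 Col replicates and measured on the remaining one, the median lay between -1.01 and -0.16 over the 3 choices. For the 71 in both, the median change was 2.29 in Col and 1.77 in bru1, and 62 had a negative interaction, 1 of them past the test. Their median interaction was -0.46, or -0.11 without bru1 52 h replicate 3 and -0.16 without Col 52 h replicate 3. HSP15.7, HSP22 and HSP17.6C are examples of genes above the control at both times in both genotypes. At least 2-fold higher at 52 h in both genotypes were 143 probe sets (3.11 for independent lists), and at least 2-fold lower 116 (2.72).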

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

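The tests of single arrays left out, of seed reserve genes, of control differences and of a difference arising after heat were chosen only after the results were seen, as were the LEA, seed reserve, flavonoid, mitochondrial and plastid lists.

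A difference between the genotypes' responses was the reason for listing the results of this part. At 4 h limma called 78 probe sets with a different response in bru1. Genes with a positive difference, the bru1 change minus the Col change, were STZ (2.86), AT2G21640 (2.24), AT3G15670 (2.08), AT1G04560 (1.76), AT3G53040 (1.66), AT1G31335 (1.63), AT4G21020 (1.54), AT3G54940 (1.46), LEA (1.43) and the auxin conjugase gene GH3.3 (1.41). Those with a negative difference were AT2G32150 (-2.13), GAT1_2.1 (-1.71), AT1G72900 (-1.59), AT5G43520 (-1.41), AT4G08780 (-1.38), the response regulator gene RR16 (-1.32), AT2G44380 (-1.23), AT3G15630 (-1.21), MSRB5 (-1.17) and BGLU33 (-1.08). At 52 h it called 27, with AT3G02480 (2.21) and AT4G36600 (1.18) positive. Negative differences were those of AT3G05600 (-2.72), AT2G18190 (-2.72), AT4G22490 (-2.25), THI2.2 (-2.03), AT1G17960 (-1.84), AT2G33850 (-1.76), AT1G66100 (-1.76), AT5G45670 (-1.55), AT5G33370 (-1.45) and AT5G43450 (-1.43). Median interactions of lists past the preset test were 0.42 for larger chaperones, 0.58 for the unfolded protein response, 0.20 for LEA genes and -0.39 for plastid genes at 4 h. At 52 h they were 0.12 for LEA genes (0.024 without bru1 52 h replicate 2 and 0.18 without bru1 control replicate 1), 1.25 for flavonoid genes (0.64 without Col 52 h replicate 3) and -0.34 for mitochondrial genes (-0.088 without Col 52 h replicate 3 and -0.10 without bru1 52 h replicate 3). None of the 7 list medians passed with an estimated correlation. Of the genes listed here, AT4G36600, AT5G33370, AT5G43520, AT3G54940, AT4G22490, AT4G21020, AT4G08780, LEA, AT2G33850 and BGLU33 had a group mean no higher than 4.39, a level not shown to be above background.

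The 25S ribosomal RNA control probe set, outside the comparisons of genes, was above the untreated controls by 1.32 (Col at 4 h), 0.77 (Col at 52 h), 2.12 (bru1 at 4 h) and 1.05 (bru1 at 52 h) on the log2 scale.

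In each of the 7 comparisons of 2 groups, 1 of the 10 splits of the 6 arrays, the real one, gave as many probe sets, and 10 splits are too few for a share under 0.05. The real totals and the highest of the other splits were 8274 and 0 (Col at 4 h), 3360 and 0 (Col at 52 h), 8957 and 1 (bru1 at 4 h) and 1647 and 33 (bru1 at 52 h). For bru1 against Col they were 2352 and 0 in controls, 3048 and 238 at 4 h, and 2615 and 455 at 52 h. For the interactions, 8 of 100 regroupings at 4 h (real 78, highest other 898) and 9 of 100 at 52 h (real 27, highest other 771) gave as many, the real one included. Because of how the arrays were exchanged, these shares cannot decide on chance, which stays open. Regroupings that call several times the real number point to a structure of the samples. Arrays were exchanged between the genotypes within a condition. An uneven exchange carries the genotype difference into the interaction, so it gives no reference without effect. Of the 44 drawn regroupings with an even exchange, 0 gave as many and limma called 0 probe sets in each, a comparison added after the counts were seen. An even exchange mixes both genotypes within each group, so their difference widens the spread and lowers the number of calls. These regroupings therefore do not exclude chance either.

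The first pattern weighed is the higher level of LEA genes in bru1, 17 of 35 at 4 h. A difference that arises only after heat is excluded for the 10 LEA genes already higher in untreated controls, but not for the rest of the list. In controls the list did not pass with an estimated correlation (camera adjusted p = 0.11). At 4 h, 5 LEA genes had a positive interaction past the test in limma, so part of the difference may arise after heat. A single array is excluded by a median of at least 0.45 with any of the 6 arrays left out (0.47 with all). A scale difference left between the deposited arrays is excluded by at least 16 called at 4 h under quantile normalisation or median centring. The arrays already had nearly equal distributions, so this does not test an effect of their original normalisation. Seed reserve material or slower seedling growth stays open. Over all 12 seed reserve genes the median difference was 0.27 in controls, with 3 genes higher and 0 lower, 0.69 at 4 h and 0.52 at 52 h. In controls it was 0.088 with an SD of 0.24 over the 8 not named otherwise, a choice that took out genes by their large changes. A separate array run per genotype also cannot be told apart from the genotype here, and the genotype itself stays among the open explanations, as untested.

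The second is that 23 of the 27 probe sets called at 52 h had a negative difference, 16 of them risen in Col past the threshold and 12 fallen in bru1. A scale difference left between the deposited arrays is excluded by at least 78.8% of calls being negative under either rescaling (85.2% as deposited). This does not test the original normalisation, since the arrays were already nearly equal in distribution. A single array is neither shown nor excluded as the cause. With the calls made anew, most were negative in all 12 refits without 1 array, 68.3% to 87.5%, but only 7 of 8 were so without Col 52 h replicate 1, and without Col 52 h replicate 2 the negative calls rose from 23 to 97 and the positive ones from 4 to 45. A difference between the untreated controls stays open, because the median control difference of these probe sets was 0.37 with an SD of 1.04.

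The last is the more negative change of plastid transcripts in bru1 at 4 h (median -0.69, against -0.37 in Col, or -0.16 there without Col 4 h replicate 2), with a median interaction of -0.39. A single array as the whole cause is excluded by -0.28 without Col 4 h replicate 1, the value nearest to 0. A scale difference left between the deposited arrays is excluded by -0.37 under rescaling, which does not test the original normalisation. A difference between the untreated controls stays open, because the median control difference was 0.14 (SD 0.37 over the genes), whereas a level lower in bru1 throughout drops out of the interaction, and 54 of the 69 genes had a positive difference in controls. In limma 0 genes of the list passed adjusted over all probe sets, 18 were lower adjusted over the list alone and 27 lay under an unadjusted p of 0.05, and the list was not past the test with an estimated correlation (adjusted p = 0.28). A difference in how much RNA without a poly(A) tail was labelled was not tested. The mitochondrial genes had a median 4 h interaction of 0.027, with 9 positive and 7 negative. The 25S ribosomal RNA control rose by 2.12 in bru1 and by 1.32 in Col at 4 h. Neither was thus lower in bru1, but these values do not cover the plastid transcripts themselves.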

How the results depend on the processing

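The fits without both 52 h arrays numbered 3 and the test of all chaperone and memory genes risen at 4 h in both genotypes were chosen only after the results were seen. Quantile normalisation, median centring, removal of dim probe sets, and trend and robust eBayes kept every count of the 9 comparisons within 1.5 times. Requiring at least 2-fold as well gave 1809 (Col at 4 h), 649 (Col at 52 h), 2134 (bru1 at 4 h), 412 (bru1 at 52 h), 357, 539 and 478 (bru1 against Col in controls, at 4 h and at 52 h) and 50 (interaction at 4 h), since fewer probe sets meet both criteria. Array weights gave 7672 (Col at 52 h), 3519 (bru1 at 52 h), 3726, 4804 and 8462 (bru1 against Col in controls, at 4 h and at 52 h), 773 (interaction at 4 h) and 1113 (interaction at 52 h), and the cause was not tested. Fits on only the groups compared gave 2201 (Col at 52 h), 1001 (bru1 against Col at 52 h), 227 (interaction at 4 h) and 14 (interaction at 52 h), and the cause was not tested. Without both 52 h arrays numbered 3 the 52 h interaction called 79. Leaving out each array in turn gave 7060 to 7363 (Col at 4 h), 2381 to 3816 (Col at 52 h), 7577 to 8205 (bru1 at 4 h), 843 to 1833 (bru1 at 52 h), 1486 to 1844 (bru1 against Col, control), 1715 to 3323 (at 4 h), 1549 to 3428 (at 52 h), 7 to 405 (interaction at 4 h) and 8 to 142 (interaction at 52 h). The lowest and highest interaction counts came without Col 4 h replicate 1 and bru1 4 h replicate 2, and without Col 52 h replicates 1 and 2. The memory list's median 52 h interaction, -0.39, ran from -0.77 (without bru1 52 h replicate 2) to 0.029 (without bru1 52 h replicate 3, sign reversed), was 0.39 without both 52 h arrays numbered 3 (sign reversed), and was -0.44 over all 13 chaperone and memory genes risen at 4 h in both genotypes. The first and last of these had preset camera p-values, not adjusted over lists, of 0.011 and 0.0012, but 0.15 and 0.27 with an estimated correlation. With an estimated correlation 8 of the 16 calls of fixed lists passed. The correlation of 52 h responses ran from 0.687 (without bru1 52 h replicate 2) to 0.738 over the arrays left out. All 3 correlations of the deviations of same-numbered arrays exceeded 0.1 in 1 of 15 group pairs (-0.505 to 0.222). The own number gave the highest correlation in 14 of 45 comparisons of an array with another group. Between control and 52 h of the same genotype it did so for all 3 arrays (0.036 to 0.158 in Col and 0.169 to 0.222 in bru1). A pairing of those arrays by number is therefore not excluded, and the main fits do not use it. With the replicate block the 4 h interaction called 28, while the other counts stayed within 1.5 times, and of the 178 calls of named genes 164 were past the threshold and 14 were not. With median centring 2 were not, and with quantile normalisation 3. At 3 arrays a group, changes near the spread between arrays and signals near the background limit what can be called.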

Other observations

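The contrast of declines, the genes sustained in both genotypes and the tests of single arrays and of a higher start were chosen only after the results were seen, and so was the pseudogene list.

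The mitotic Aurora kinase genes AUR1 and AUR2 fell by 0.65 and 0.88 in Col at 4 h and by 0.72 and 1.14 in bru1 (SE 0.20 and 0.18). MCM7, a subunit of the replicative helicase, fell by 0.60 in Col and 0.36 in bru1 at 4 h, and ICU2, a subunit gene of DNA polymerase alpha, by 0.53 in bru1. At 52 h MCM7 (-0.38 ± 0.12) and AUR2 (-0.57 ± 0.18) were lower in bru1 than in Col. The root hair expansin genes EXPA7 and EXPA18 fell by 1.18 and 1.29 in Col at 4 h. Both also fell in bru1 at 4 h and in Col at 52 h, and 1 of the 2 fell in bru1 at 52 h. EXPA18 was higher in bru1 than in Col in controls (0.88 ± 0.24), at 4 h (0.98 ± 0.24) and at 52 h (1.08 ± 0.24). The guard cell regulator gene FAMA was lower in bru1 at 4 h (-0.77 ± 0.11).

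The clock gene GI rose by 2.51 ± 0.22 in Col and 3.73 ± 0.22 in bru1 at 4 h, and the difference of 1.22 ± 0.31 did not pass the test (adjusted p = 0.11). Of the cold and dehydration genes, COR47 rose at 4 h in both genotypes (2.06 and 2.25), while COR15A rose at 52 h (1.87 and 2.24) with 0.20 and 0.84 at 4 h, neither past the test. Of the 3 photosynthesis genes LHCB4.1 (0.28) and LHCB4.2 (1.01) rose in bru1 at 4 h, or 2 adjusted over the list alone, with a list median of 0.28 (camera adjusted p = 0.11). QQS (0.16) and the stem cell gene CLV3 (-0.17) did not pass the test in Col at 4 h. Of 989 pseudogenes 26 rose and 15 fell in Col at 4 h, and 35 rose and 7 fell in bru1, with medians of -0.01 and 0.01.

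The heat stress memory list gave a median 52 h interaction of -0.39, and 46 of 100 regroupings gave a median at least as far from 0 (highest other 0.996). Of the 44 with an even exchange, which leave out a constant genotype difference, 21 did, so chance is not excluded. A hypothesis formed on these data is that chaperone transcripts decline further from 4 h to 52 h in bru1. All 13 chaperone and memory genes risen at 4 h in both genotypes had a negative difference of declines, from -2.22 to -0.10 with a median of -0.74. In limma 0 of them passed, and over all probe sets 46 passed with a positive and 85 with a negative difference. In the whole lists, 3 of the 10 small heat shock protein genes and 5 of the 8 larger chaperone genes lay under an unadjusted p of 0.05. The memory, small heat shock protein and larger chaperone lists passed at the preset correlation (camera adjusted p = 0.039, 0.0037 and 8.5e-05). None passed with an estimated correlation (camera adjusted p = 0.34, 0.29 and 0.29). Chance is not excluded, with 16 of 100 regroupings as far from 0 (highest other 0.996), and 7 of the 44 with an even exchange. A single array as the whole cause is excluded by medians of -0.45 without bru1 52 h replicate 3 and -0.49 without Col 52 h replicate 3. The decline was not refitted without both of these arrays. Leaving out both reversed the sign of the memory list's median 52 h interaction, so the 2 arrays together stay open as a cause. A higher start at 4 h in bru1 stays open, since the median bru1 against Col difference of these genes was 0.30 at 4 h and -0.44 (SD 0.38) at 52 h.

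A further hypothesis is that the 71 genes sustained in both genotypes have a smaller 52 h response in bru1, with a median interaction of -0.46. Their median 4 h responses were 4.15 in Col and 4.66 in bru1. It may rest on a single array, because without bru1 52 h replicate 3 the median was -0.11. Chance is not excluded, with 34 of 100 regroupings as far from 0 (highest other 0.725), and 19 of the 44 with an even exchange.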
